A study of Oryza sativa with 11 samples.

How the data were processed

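Single-nucleus RNA profiles were read from 11 libraries of rice, each made from the nuclei of 1 developing leaf, the third of its seedling, taken from the shoot apex up to the green tip, and dissected early in the light period, per the labels' protocols. Each library has its own deposited matrix of UMI counts per gene and nucleus, made with 10x 3' chemistry per the labels' protocols. The values are whole numbers with different totals per library, per the file headers and the values themselves. The submitters' processing notes name the IRGSP-1.0 build and Seurat 5.1.0. The aligner, the counting program, the annotation release and the filters are not given in the sources used here. The genes listed and the smallest and largest UMI totals per nucleus differ between the deposited matrices, so genes and nuclei had already been filtered, with limits that differ by library.

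A gene that a library's matrix did not list was taken as 0 in it, except for 278 genes whose level in the other libraries called for at least 20 UMIs there. Those genes were left out, which removed 0.124% of all UMIs and left 34615 of 34893 genes. The 96 plastid and mitochondrial genes were kept and treated as a list of their own. Pairs of libraries from the same group differed far beyond sampling noise (chi-square per degree of freedom of at least 67.2 over genes), so none was a copy of another. Each counted as a replicate because the labels number it as a replicate and say that each library is a separate leaf sample. The p-values of edgeR, limma and the exact permutation tests measure the spread between these libraries. Camera sets the genes of a list against the other genes, so at its preset correlation its p-values do not measure that spread.

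The matrices give gene identifiers without symbols, and the reference gene table (assembly ASM3414082v1) matched by identifier for 1 gene only. Symbols therefore come from 207 pairs of symbol and identifier written before the data were examined. Of these, 123 were kept because the table holds the symbol on the chromosome that the identifier names, 12 were dropped, and 72 symbols were not in the table. The rule that keeps a pair was added after the table was seen. Other nuclear genes are given by identifier, at most 2 that rose and 2 that fell per comparison. No genomic coordinates are given, since the table's assembly is not the build of the matrices. The guard cell list had no usable member, and lists that needed gene descriptions could not be formed. Reads shared between close relatives, such as RAB16B, RAB16C and RAB16D on 1 chromosome, or DREB1A and DREB1B, may have been split between them by the counting, so single members of such families are uncertain.

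UMI counts were summed over all nuclei of each library. Genes were tested with edgeR 4.0.16 (R 4.3.3): TMM scaling, filterByExpr, and the quasi-likelihood test with Benjamini-Hochberg adjustment at 0.05. All 11 libraries entered each fit. One fit pooled the severities of each stress (well-watered, drought and salinity, with batch, as numbered in the labels, as a term) and the other held 5 groups with batch as a term, which leaves 4 residual degrees of freedom. CPM values come from edgeR's cpm function and scale the UMI counts of a gene by the library total over the genes kept, itself adjusted by TMM. Mean log2 CPM of lists uses a prior count of 2, and single genes were set beside their batch as log2 of CPM plus 0.5. Fitted folds are log2 values. Their standard errors (SE) were derived from the test, as the size of the log2 fold divided by the square root of the quasi-likelihood F statistic.

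Doublets were scored with Scrublet in scanpy 1.11.5, and the highest-scoring nuclei were called up to an expected share that grows by 0.008 for each 1000 nuclei, in all 15217 of 142567 nuclei (10.7%). The threshold that Scrublet sets by itself was not used, because it called under 0.01% of nuclei in 4 libraries. The remaining 127350 nuclei, all with at least 500 UMIs, were clustered on 2000 variable genes centred within libraries, 30 principal components and 20 neighbours, with Leiden (leidenalg 0.10.2) at a resolution of 0.6. A cluster of the 25 was given a class name where at least 3 markers, and at least 0.5 of its list, were raised 2-fold over the other clusters at a CPM of at least 5, and where no other class had more markers among its 10 leading genes. This named 15 clusters in 5 classes, which held 60.7% of the nuclei. The other 10 clusters are given by number, and their shares of nuclei are in the report. Each class held by all 11 libraries with at least 50 nuclei was summed per library and tested with edgeR as above, 13 classes in all. The class names are "like" names that rest on the fixed markers, and the study's own cell types were not used here. The share of free RNA in droplets was not measured, so markers of one class are not named as changed inside another. The rule for doublets, the rule for naming clusters and the rule for leaving out genes were set after the data were seen.

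The difference between the responses of epidermis-like and mesophyll-like nuclei was tested with limma 3.58.1 on log2 CPM (prior count 2) within libraries. Shares of nuclei and mean log2 CPM of gene lists were compared with 2-sided exact permutation tests over libraries. The 19 gene lists were tested with camera at a preset correlation of 0.01 between genes and with an estimated correlation. They were also tested with fry, whose results are not given here. The lists and their members were written before the data were examined. Drought and salinity share their well-watered libraries, so 100 simulated data sets of unchanged groups against the same controls stand beside the overlap of these responses, and 25 beside each of its alternatives. Fits of single severities inside classes, the exact tests of list means and the tests of lists between classes were added after the data were seen.

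Genes are named by rules written before the data were examined. A pooled comparison against well-watered names up to 10 genes in each direction, and each other comparison or class up to 3. A named gene has an adjusted p under 0.05, a mean CPM of at least 5 and the same sign in every stressed library against the well-watered library of its batch. Each list names up to 4 members past the threshold or, where none passes, the 2 with the highest mean CPM. The rule asked for a symbol or description in the reference, and the 123 pairs took its place because of the missing match. Genes named outside these rules are said to have been chosen after their values were seen.

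The tests were also run on simulated counts with known folds. With the drought libraries, edgeR recovered 28% of 100 genes changed 2-fold and 92% of 100 changed 4-fold, with 4 false calls among 124. DESeq2 1.42.0 recovered 61% and 97%, with 49 false calls among 207. For moderate drought, edgeR recovered 21% and 93%, with 12 false calls among 126. Inside mesophyll-like and meristem-like nuclei edgeR recovered 19% and 14% of 2-fold changes under drought, and 89% and 81% of 4-fold changes. The limma test of a difference between classes under salinity recovered 1.01% of 2-fold and 52.0% of 4-fold differences. For drought, camera called the simulated list and 0 of 18 unchanged lists. Simulated genes were drawn independently of each other, so these runs cannot test camera's preset correlation between genes.

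Alternatives were DESeq2, no batch term, the replicate number as a block, only the libraries compared, no filter on low counts, called doublets kept, at least 1000 UMIs per nucleus, a finer clustering, another prior count and leaving out each library. Further ones were added after the data were seen: 2 treatments of unlisted genes, only batches 2 and 3, and leaving out the 3 libraries in which the clock gene GI lay furthest below the well-watered library of its batch (log2 −3.05 or lower).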

Results

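Single-nucleus RNA counts were collected from rice (cultivar Nipponbare) in 11 libraries, each from 1 leaf, the third of its seedling and still developing. The plants were well-watered or grew under drought or salinity, each stress at 2 severities. The soil held 3 g of water per g in the well-watered and salinity groups, 1.5 g under mild drought and 1 g under moderate drought, and the water of the salinity groups held 100 mM (mild) or 200 mM (moderate) NaCl. The 3 well-watered libraries came from batches 1, 2 and 3, the 2 mild drought libraries from batches 1 and 2, and the 2 libraries of each of the other groups from batches 2 and 3, as the labels number them. Total UMIs were 17514203, 30703262 and 40891380 in well-watered replicates 1 to 3, 22149159 and 21501342 under mild drought, and 47334897 and 29360737 under moderate drought. Mild salinity gave 33514833 and 30907815 UMIs, and moderate salinity 34452097 and 34829317. Between 10609 and 17991 nuclei per library were deposited, 142567 in all, with a median of 1037 to 2032.5 UMIs per nucleus.

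The nuclei fell into 25 clusters, 15 of which matched fixed markers of 5 classes. Proliferating-like nuclei made up 17.8% of all nuclei, epidermis-like 14.6%, mesophyll-like 13.5%, secondary wall-like 8.22% and meristem-like 6.63%. In mesophyll-like nuclei the antenna protein gene CAB1R stood at 3254 ± 954 CPM (SD over 11 libraries) and RCA, for Rubisco activase, at 1768 ± 953. Epidermis-like nuclei held 227 ± 53.4 CPM of ROC5, an epidermal homeobox gene, and proliferating-like nuclei 208 ± 36.1 CPM of PCNA, the sliding clamp of DNA replication. Secondary wall-like nuclei held 1038 ± 138 CPM of COMT1, of lignin synthesis, and meristem-like nuclei 141 ± 63.2 CPM of OSH1, a KNOX homeobox gene. Of the unnamed clusters, cluster 1 held 16.3% of nuclei, cluster 5 held 6.85%, cluster 9 held 4.55%, cluster 11 held 2.99%, cluster 13 held 2.77%, and clusters 16, 18, 19, 23 and 25 held 1.75%, 1.74%, 1.56%, 0.470% and 0.242%.

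The first comparison asks what drought, both severities together, changed in whole leaves (4 libraries against 3 well-watered). The abscisic acid and dehydration list rose: all 16 measured members were higher, by a mean log2 of 1.82 (camera, adjusted p = 3.72e-09, and adjusted p = 0.459 with an estimated correlation). Its members with the highest counts were the dehydrin DHN1 at 0.33 (SE 0.68) and the protein phosphatase PP2C09 at 0.60 (SE 0.35). Cell division genes fell: all 11 proliferating markers were lower, by a mean of −0.58 (adjusted p = 5.47e-08, and adjusted p = 0.258 with an estimated correlation), with PCNA at −0.75 (SE 0.30) and the B-type cyclin CYCB2;2 at −0.59 (SE 0.31), while proliferating-like nuclei were 12.2% to 17.6% of nuclei under drought and 18.4% to 21.2% when well-watered. The sodium and potassium transport list (mean 0.74) and the vascular list (mean 0.63) rose, with 7 of 7 members higher in both, adjusted p = 0.0325 each, and adjusted p = 0.258 with an estimated correlation. The sodium transporter HKT1;1 was at 0.91 (SE 0.41) and the sucrose transporter SUT1 at 0.35 (SE 0.21). By single genes edgeR called 0 of 27129 for drought, with 2051 at an unadjusted p under 0.05, and DESeq2 called 286. Adjusted over the list alone, 2 abscisic acid genes and 1 gene each of the aquaporin, epidermis and secondary wall lists passed. Chosen after its values were seen, the tonoplast aquaporin TIP1;2 stood at 34.6 ± 20.7 CPM in drought (SD, n = 4) and 7.51 ± 7.45 in well-watered libraries (n = 3). Its log2 fold was 2.10 (SE 0.25, edgeR adjusted p = 0.105), and it was above the well-watered library of its batch in 4 of 4.

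The abscisic acid list differed between batches, as the plot of gene lists by library shows. Its mean log2 CPM was 4.81 in moderate drought replicate 1 against 1.21 in the well-watered library of the same batch 2, and 3.35 in replicate 2 against 1.57 in batch 3. Mild drought was at 2.93 in replicate 2 against the same 1.21 of batch 2, and at 2.60 in replicate 1 against 2.46 in batch 1. The clock gene GI was far lower in moderate drought replicate 1 (12.3 CPM), mild salinity replicate 1 (8.87) and moderate salinity replicate 1 (13.5) than in the well-watered library of the same batch 2 (116). The morning gene LHY was higher in them (3239, 3913 and 2468 CPM against 1543). Without these 3 libraries, an alternative added after the data were seen, edgeR called 396 genes for drought (170 up and 226 down), among them TIP1;2 (2.05), PP2C08 (1.91), PCNA (−0.97) and CYCB2;2 (−0.86). The abscisic acid (adjusted p = 3.77e-06) and proliferating lists (2.60e-12) then still passed camera, as did the vascular list (0.0391), and the sodium and potassium list no longer did (0.132). Secondary wall genes (higher, 0.0201), aquaporins (lower, 0.0201) and organelle-encoded genes (lower, 0.00222) passed there too. Organelle transcripts among nuclei are largely carried over in preparation, and made up 2.41% to 4.81% of UMIs in the well-watered libraries alone, so changes of that list, here and below, are not taken as responses. With only batches 2 and 3 jasmonate genes passed (higher, 0.00432). Both alternatives were tested at camera's preset correlation only. The proliferating call held without any 1 library, and the abscisic acid call ended without well-watered replicate 2 (adjusted p = 0.0997). The transport and vascular calls ended without well-watered replicates 2 or 3, moderate drought replicate 2 or moderate salinity replicate 2 (up to 0.134 and 0.188). Without mild drought replicate 2, edgeR called 6 genes.

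**Figure D1:**
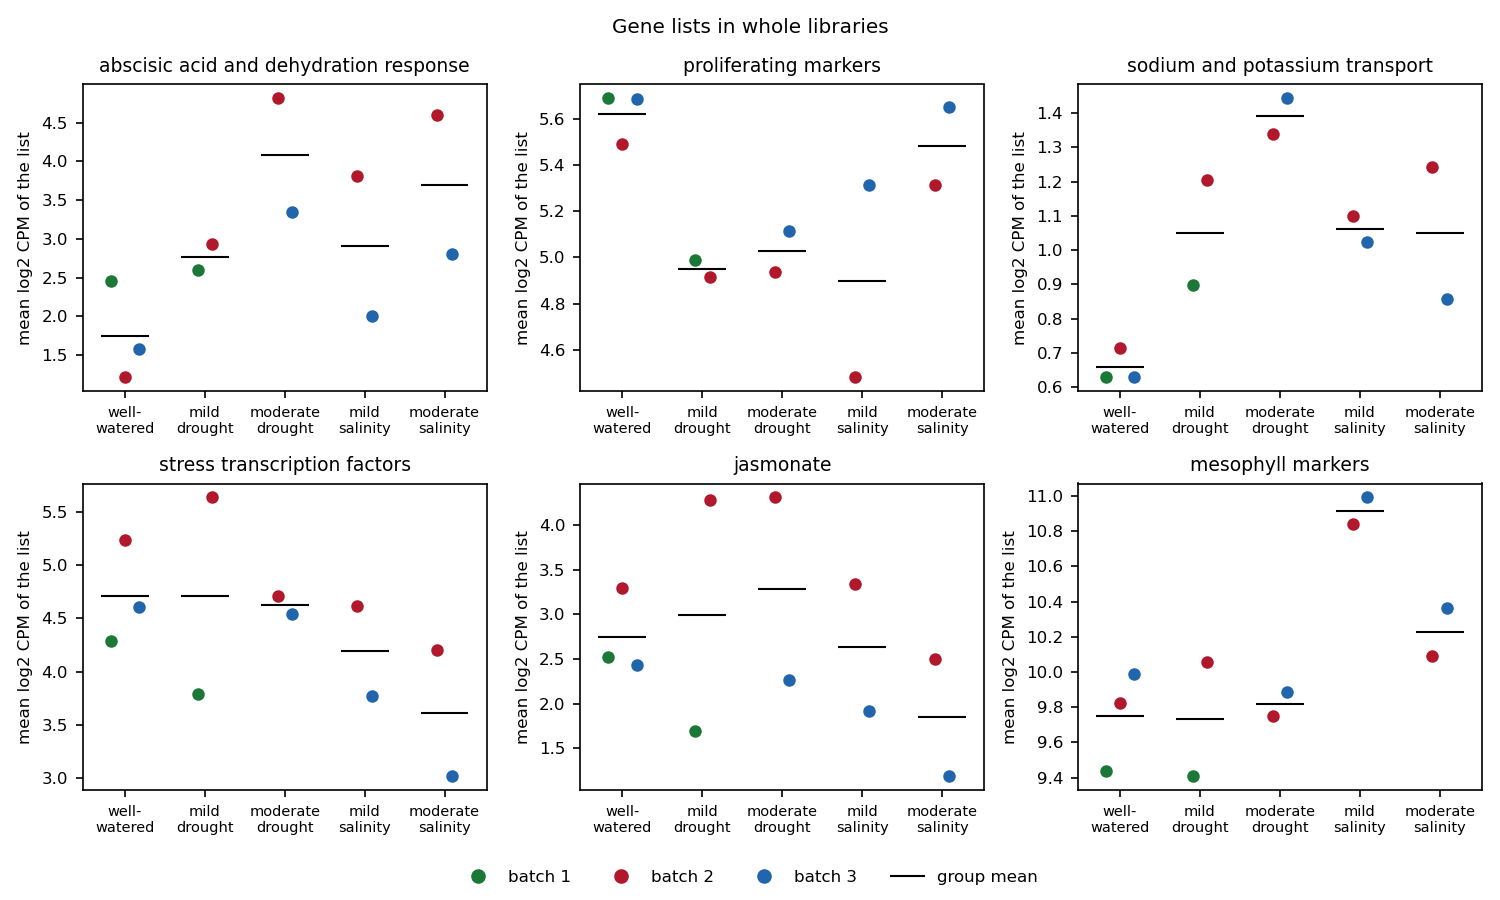
Mean log2 CPM of 6 gene lists (y axis) in each library, by group, coloured by batch, with lines at group means. The abscisic acid list lies between 1.21 and 2.46 in the well-watered libraries and reaches 4.81 under moderate drought.

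**Figure D2:**
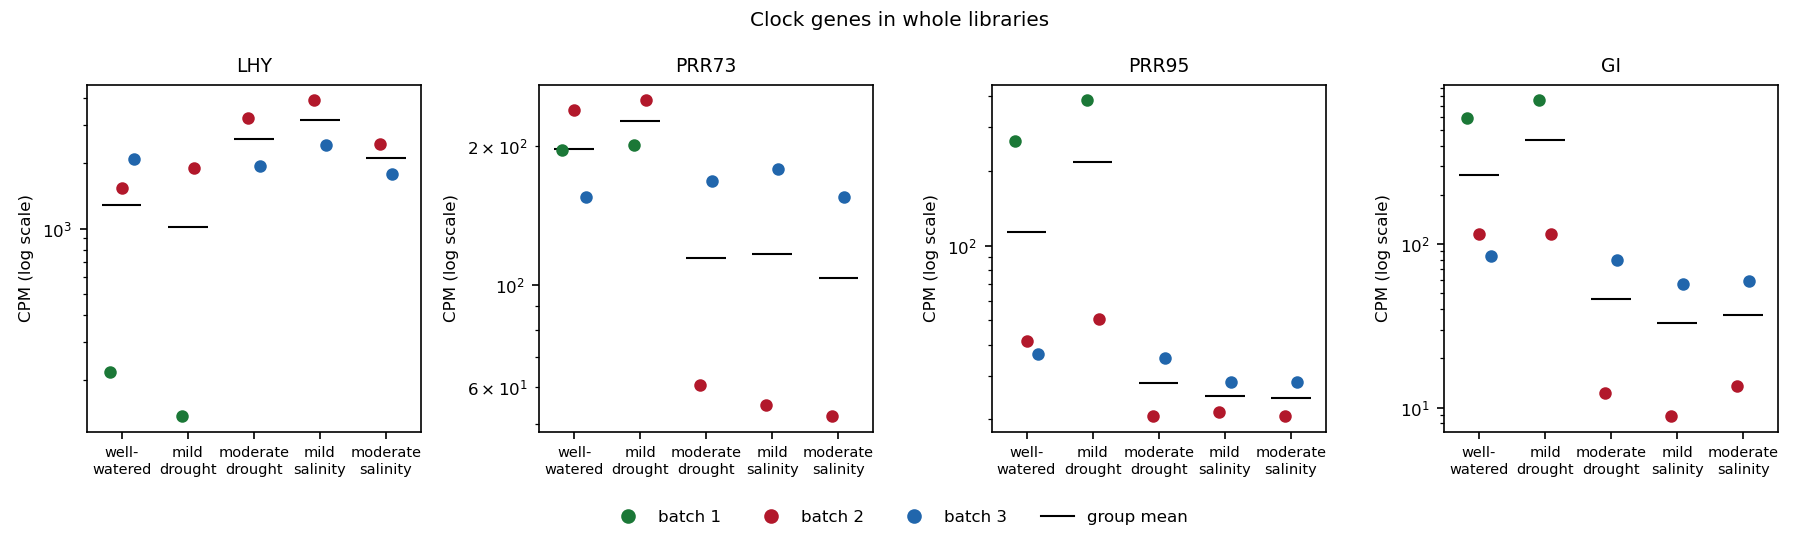
CPM of 4 clock genes on a log axis in each library, by group, coloured by batch, with lines at group means. GI lies between 8.87 and 13.5 CPM in moderate drought, mild salinity and moderate salinity of batch 2, and at 56.8 CPM or more elsewhere.

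With all libraries the other lists did not pass camera for drought. Secondary wall genes were higher in 5 of 5 (mean 0.27, adjusted p = 0.0941), with the lignin gene CAD2, singled out after its values were seen, at 0.64 (SE 0.17), and passed without moderate drought replicate 1 (0.0287). Organelle-encoded genes were lower in 64 of 96 (mean −0.12, 0.0558) and passed without any 1 of 5 libraries: well-watered replicate 2, either moderate drought library, mild salinity replicate 2 or moderate salinity replicate 1. The other means were 0.24 for primary wall and expansion (0.340), 0.07 for compatible solutes (0.473), 0.16 for epidermis (0.752), 0.21 for jasmonate (0.752) and −0.10 for the clock (0.868). They were 0.03 for growth regulators (0.914), 0.08 for photosystem and antenna (0.914), −0.06 for reactive oxygen scavenging (0.914), −0.09 for aquaporins (0.917) and 0.05 for carbon fixation and photorespiration (0.917). Mean and test or median differed in sign for meristem (mean 0.08, median −0.05, test down, 0.926), mesophyll (0.01, −0.05, down, 0.965) and stress transcription factors (−0.14, 0.04, down, 0.752). The aquaporins PIP2;1 and PIP1;1 stood at −0.34 (SE 0.40) and −0.26 (SE 0.25). Calls also appeared when 1 library was left out: jasmonate without well-watered replicate 1 or mild drought replicate 1, primary wall without well-watered replicate 3, and stress factors without mild drought replicate 2.

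The second comparison asks the same of salinity (4 libraries against 3). The few photosynthesis genes measured were higher, mostly under mild salinity: RCA and GLO1, for glycolate oxidase, were at 1.04 (SE 0.36) and 0.82 (SE 0.26), higher in 4 of 4 libraries than in their batch, and the antenna genes CAB2R and CAB1R at 0.68 (SE 0.29) and 0.38 (SE 0.27). The carbon fixation list (2 of 2 higher, mean 0.93, adjusted p = 0.0051), the mesophyll markers (3 of 3, 0.70, 0.00676) and the photosystem list (3 of 3, 0.60, 0.00739) passed camera, each with adjusted p = 0.306 with an estimated correlation, and share RCA, CAB1R and CAB2R in part. Most members of these lists have no symbol in the gene table, so each rests on 2 or 3 genes. Under moderate salinity alone none of the 3 passed (means 0.41, 0.28 and 0.24, adjusted p = 0.347, 0.485 and 0.485), against 1.31, 0.97 and 0.84 under mild salinity. Mesophyll-like nuclei were 19.7% and 16.99% of nuclei under mild salinity and 12.3% and 12.4% under moderate salinity, against 8.52% to 14.2% when well-watered. Abscisic acid genes rose (15 of 16 higher, mean 1.62, 1.58e-09, and adjusted p = 0.306 with an estimated correlation), with DHN1 at 0.70 (SE 0.71) and PP2C09 at 0.86 (SE 0.37). Stress transcription factors fell (5 of 7 lower, mean −1.03, 0.000466, and adjusted p = 0.230 with an estimated correlation), with the factors NAC5 at −1.55 (SE 0.51) and NAC6 at −0.86 (SE 0.40), each below its batch in 4 of 4. The jasmonate list fell (6 of 7 lower, mean −0.81, 0.000466, and adjusted p = 0.306 with an estimated correlation), with the JAZ repressor genes TIFY11B at −0.78 (SE 0.34) and TIFY10A at −0.63 (SE 0.27).

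Proliferating markers fell under salinity too (9 of 11 lower, mean −0.40, camera adjusted p = 0.00133), as did the clock (4 of 5 lower, −0.71, 0.0366), with GI at −1.87 (SE 0.79) and LHY at 0.31 (SE 0.39). The fall of proliferating markers came mostly from mild salinity, at 4.48 and 5.32 mean log2 CPM against 5.49 and 5.69 in the well-watered libraries of the same batches, while under moderate salinity they were at 5.31 and 5.65 and not past (camera adjusted p = 0.494). Aquaporins (10 of 13, 0.22, 0.0366) and organelle-encoded genes (73 of 96, 0.18, 0.018) were higher. These 4 had adjusted p = 0.309, 0.306, 0.501 and 0.809 with an estimated correlation, so that none of the 10 lists passed with it. Adjusted over the list alone, 3 abscisic acid, 3 stress factor, 2 carbon fixation genes and 1 gene each of the jasmonate, mesophyll, photosystem and aquaporin lists passed. By single genes edgeR called 0 of 27129 for salinity, with 2322 at an unadjusted p under 0.05, and DESeq2 called 318. Without moderate drought replicate 1 edgeR called 2 genes, and without mild drought replicate 2 it called 1. DREB1A was at −2.38 (SE 0.73) and TIFY11D at −1.53 (SE 0.44), both chosen after their values were seen.

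Abscisic acid, jasmonate, stress factor and carbon fixation calls for salinity held when any 1 library was left out. Mesophyll and photosystem calls ended without either mild salinity library (adjusted p up to 0.0583), the proliferating call without mild salinity replicate 1 (0.0639), and the clock call without well-watered replicate 2 or either batch 2 salinity library (up to 0.215). The aquaporin call ended without well-watered replicate 2, mild drought replicate 2 or either mild salinity library (up to 0.350), and the organelle call without well-watered replicates 2 or 3 or either mild salinity library (up to 0.751). Without the 3 libraries of low GI, edgeR called 0 genes for salinity (1766 at an unadjusted p under 0.05), and the clock list no longer passed (0.363), which the choice of libraries by GI, a gene of that list, largely fixed. The aquaporin and organelle lists turned there from higher to lower, neither past (0.718 and 0.403), in this pooled fit. The lists that did not pass were vascular (mean 0.53, 0.168), growth regulators (−0.17, 0.264), epidermis (−0.12, 0.274, ROC5 at −0.33, SE 0.20), sodium and potassium transport (0.53, 0.359) and secondary wall (−0.04, 0.956). Signs differed for compatible solutes (mean −0.09, median 0.12, test up, 0.952), meristem (0.09, 0.25, down, 0.952), primary wall (0.18, −0.01, up, 0.510) and reactive oxygen scavenging (−0.21, 0.11, down, 0.952). Growth regulators passed without well-watered replicate 3 or moderate salinity replicate 1 (0.0216 at the lowest), and primary wall without well-watered replicate 3 (0.0238).

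The third comparison asks where salinity and drought differed (4 libraries each). Jasmonate genes were lower under salinity in 6 of 7 (mean −1.01, camera adjusted p = 4.82e-06, and adjusted p = 0.285 with an estimated correlation), with TIFY10A at −0.89 (SE 0.25) and TIFY11B at −0.81 (SE 0.31). Stress factors were lower in 7 of 7 (−0.90, 0.00479, and adjusted p = 0.285 with an estimated correlation), with NAC5 at −0.69 (SE 0.47) and NAC6 at −0.52 (SE 0.37). The photosynthesis genes measured were higher under salinity, with RCA at 1.10 (SE 0.32), GLO1 at 0.66 (SE 0.23), CAB1R at 0.55 (SE 0.25) and CAB2R at 0.42 (SE 0.26). The mesophyll (mean 0.69, 0.00479), carbon fixation (0.88, 0.00506) and photosystem lists (0.52, 0.0141) passed, with adjusted p = 0.285, 0.285 and 0.365 with an estimated correlation. Aquaporins (11 of 13, 0.32, 0.0204) and organelle-encoded genes (71 of 96, 0.30, 4.82e-06) were also higher under salinity, with adjusted p = 0.470 and 0.566 with an estimated correlation, and the aquaporin PIP2;1 at 0.61 (SE 0.37). Adjusted over the list alone, 5 jasmonate, 2 carbon fixation, 1 stress factor and 1 mesophyll gene passed, and edgeR called 0 of 27129 genes for salinity against drought (2993 at an unadjusted p under 0.05, DESeq2 174).

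Jasmonate and stress factor calls between salinity and drought held without any 1 library. Without mild salinity replicate 1 the carbon fixation, mesophyll and organelle lists ended at adjusted p = 0.0638, 0.0636 and 0.0636. The photosystem list ended without either mild salinity library or moderate drought replicate 1 (up to 0.126), and aquaporins ended without mild drought replicate 2 or mild salinity replicate 1 (up to 0.204). All 7 lists still passed without the 3 libraries of low GI, where edgeR called 0 genes (3196 at an unadjusted p under 0.05), and without moderate drought replicate 1 edgeR called 2. Not past with all libraries were epidermis (5 of 5 lower, −0.28, 0.0765), secondary wall (5 of 5 lower, −0.32, 0.0820), the clock (−0.61, 0.116), growth regulators (−0.21, 0.116) and proliferating (0.17, 0.182). Nor did sodium and potassium transport (−0.20, 0.228), compatible solutes (−0.16, 0.441), vascular (−0.10, 0.572), primary wall (−0.06, 0.659) or meristem (0.02, 0.992). Signs differed for the abscisic acid list (mean −0.20, median 0.12, test up, 0.572) and reactive oxygen scavenging (−0.15, 0.02, up, 0.798). Without the libraries of low GI proliferating (higher, 0.000106), primary wall (lower, 0.0101), secondary wall (lower, 0.0282), epidermis (lower, 0.0289) and vascular genes (lower, 0.0439) passed at camera's preset correlation, and with only batches 2 and 3 growth regulators did (lower, 0.0418). Without 1 library some of these passed: the abscisic acid list, the clock and secondary wall without moderate drought replicate 1 (0.0462, 0.0462 and 0.0475) and proliferating without mild salinity replicate 1 (0.00114). Epidermis passed without mild drought replicate 2 or moderate salinity replicate 1 (0.0361 at the lowest). Growth regulators passed without well-watered replicate 1, either mild drought library or moderate salinity replicate 1 (0.00507 at the lowest).

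Per library, the exact permutation test (2-sided) of list means passed for 0 of 19 lists in each pooled comparison after adjustment. It ignores the batches, and for drought, salinity and the difference between them the smallest p possible, 0.0286, nearly fixes the 0 in advance. For drought, the proliferating list was at 4.99 ± 0.09 mean log2 CPM (SD, n = 4) against 5.62 ± 0.11 (n = 3), below in 4 of 4, exact permutation p = 0.0286, which is the smallest that 35 arrangements allow, and 0.362 adjusted. For salinity, the reactive oxygen scavenging list was at 6.49 ± 0.07 against 6.86 ± 0.39, but well-watered replicate 1, in a batch without salinity libraries, was at 7.30 and the other well-watered libraries at 6.70 and 6.57, and within their own batches the 4 salinity libraries were lower by only −0.17 to −0.10. For salinity against drought the mesophyll markers were at 10.57 ± 0.42 against 9.77 ± 0.27, above in 4 of 4. Both had an exact permutation p of 0.0286 (0.271 and 0.362 adjusted). Over all 8 stressed libraries the sodium and potassium transport list was at 1.14 ± 0.21 against 0.66 ± 0.05, exact permutation p = 0.00606 and 0.115 adjusted, higher in 8 of 8. A mean log2 CPM of 0.66 is low, so members with few counts weigh on this list. The abscisic acid list (higher in 8 of 8, exact permutation p = 0.0303) and the proliferating list (lower in 8 of 8, 0.0424) had 0.259 adjusted.

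The next comparisons ask what each severity did. Moderate drought raised the dehydration genes themselves. LEA3-1, a late embryogenesis abundant protein gene, stood at 40.8 ± 9.29 CPM (SD, n = 2) against 0.461 ± 0.448 (n = 3), a log2 fold of 6.76 (SE 0.79, edgeR adjusted p = 0.0168). The dehydrin RAB16B rose by 5.47 (SE 0.50, 0.00943), RAB16C by 5.00 (SE 0.47, 0.00943) and PP2C08, of the phosphatases that act in abscisic acid signalling, by 2.73 (SE 0.42, 0.0474). TIP1;2 rose by 2.33 (SE 0.26, 0.0159), and RAB16D rose from 0.0432 ± 0.0392 to 7.49 ± 1.78 CPM, with no fold given because its well-watered counts were 1, 0 and 3. Well-watered counts were also few for LEA3-1 (18, 3 and 13), RAB16C (58, 3 and 4) and RAB16B (80, 14 and 25). The size of their folds, here and below, is therefore uncertain. Moderate drought changed 148 of 27686 genes (133 up and 15 down), among those falling Os10g0552700 by −3.32 (SE 0.33, 0.0118) and Os12g0214700 by −2.22 (SE 0.35, 0.0480). Among those rising, Os04g0445100 was at 591 and 102 CPM in the 2 libraries against 0.306 or less when well-watered. Os02g0546600 followed the libraries of low GI, at 145 CPM in moderate drought replicate 1, 55.5 and 43.4 in the batch 2 salinity libraries and 0.282 or less elsewhere. PP2C68 and PP2C30, also of the abscisic acid list and singled out after their values were seen, were at 88.2 and 68.1 CPM in moderate drought replicate 1 and at 4.01 and 5.34 in replicate 2. As lists, abscisic acid genes rose (16 of 16, mean 2.63, camera adjusted p = 1.37e-24, and adjusted p = 0.370 with an estimated correlation), 5 of them past and 9 past adjusted over the list alone. Proliferating markers fell (10 of 11, −0.60, 3.83e-05, and adjusted p = 0.486 with an estimated correlation), 6 of them past adjusted over the list alone.

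The moderate drought count moved with every library left out: it was 19 and 26 without moderate drought replicates 2 and 1, and 33 and 34 without mild drought replicates 1 and 2. It was 33, 53 and 2639 without well-watered replicates 1, 2 and 3, 66 and 75 without the mild salinity and 78 and 79 without the moderate salinity libraries. RAB16C was past in 10 of 11 such fits (lost without moderate drought replicate 1, 0.0539), and RAB16B and LEA3-1 in 9 (lost without either moderate drought library, up to 0.0553 and 0.107). TIP1;2 was past in 6 (lost without well-watered replicate 1 or any 1 drought library, up to 0.101). RAB16D was past in 3 fits and PP2C08 in 1, that without well-watered replicate 3, and all 6 genes kept their sign. Both list calls held in all 11. Leaving out the low GI libraries leaves 1 moderate drought library, in batch 3, so only log2 folds are given for it. They were 4.48 for RAB16B, 2.77 for TIP1;2, 4.85 for RAB16C, 6.67 for LEA3-1 and 2.13 for PP2C08. With only batches 2 and 3 edgeR called 36 genes, of which 35 were shared. RAB16D and PP2C08 were not past there (edgeR adjusted p = 0.0705 and 0.158). Both alternatives were added later. With no batch term edgeR called 1, and with the replicate block in place of batch 0.

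Moderate salinity raised the same dehydrin genes, RAB16B by 4.85 (SE 0.50, edgeR adjusted p = 0.0150) and RAB16C by 4.89 (SE 0.47, 0.0130), with LEA3-1 at 5.47 (SE 0.77, 0.0377) and PP2C08 at 3.19 (SE 0.43, 0.0332). DREB1A, a transcription factor gene of cold and drought responses, fell from 25.3 ± 19.5 CPM (SD, n = 3) to 2.13 ± 0.0556 (n = 2), a log2 of −4.06 (SE 0.57, edgeR adjusted p = 0.0377). Moderate salinity changed 97 genes (78 up and 19 down), among them Os05g0343400 (−3.17, SE 0.48, 0.0485) and Os08g0202300 (−2.88, SE 0.44, 0.0489), while Os03g0305600 was at 68.7 and 7.94 CPM in the 2 libraries against 0.373 or less when well-watered. Abscisic acid genes rose as a list (15 of 16, mean 2.21, camera adjusted p = 4.89e-18, and adjusted p = 0.314 with an estimated correlation, 4 past and 10 past adjusted over the list alone). Stress factors fell (6 of 7, −1.43, 0.000249, and adjusted p = 0.268 with an estimated correlation), 1 past and 4 past adjusted over the list alone. Jasmonate genes fell (7 of 7, −1.29, 0.000249, and adjusted p = 0.624 with an estimated correlation), 4 past adjusted over the list alone, but not without well-watered replicate 3 (0.0690).

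Single libraries moved the moderate salinity count as well: it was 1 and 20 without moderate salinity replicates 1 and 2, and 10 without either mild drought library. It was 9, 56 and 4804 without well-watered replicates 1, 2 and 3, 49 and 53 without the mild salinity libraries and 52 without moderate drought replicate 2. RAB16C was past in 9 of 11 such fits (lost without either moderate salinity library, up to 0.0769) and RAB16B in 6 (lost without well-watered replicate 1, either mild drought or either moderate salinity library, up to 0.191). DREB1A was past in 3, LEA3-1 in 2 and PP2C08 in 1. Without the low GI libraries 1 moderate salinity library is left, in batch 3, so only log2 folds are given for it. DREB1A was at −3.37, RAB16B at 3.48, RAB16C at 5.33, PP2C08 at 2.04 and LEA3-1 at 4.89, each with its sign kept. With no batch term edgeR called 2, and with only batches 2 and 3, or with the replicate block in place of batch, 0.

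Under mild salinity photosynthesis genes were higher, in libraries with more mesophyll-like nuclei (19.7% and 16.99%, against 8.52% to 14.2% when well-watered, not tested by severity). RCA was at 1.48 (SE 0.25, edgeR adjusted p = 0.0792) and GLO1 at 1.14 (SE 0.17, 0.0784), neither past the threshold. Their lists rose: carbon fixation (mean 1.31, camera adjusted p = 2.49e-06), mesophyll (0.97, 7.49e-05) and photosystem (0.84, 0.000134), each with adjusted p = 0.0914 with an estimated correlation. Adjusted over the list alone, 2, 3 and 3 of their members passed. Proliferating markers fell (11 of 11, mean −0.72, 2.91e-07, and adjusted p = 0.203 with an estimated correlation), with proliferating-like nuclei at 12.9% and 17.6% against 18.4% to 21.2% when well-watered. Abscisic acid genes (mean 1.39, 7.55e-10) and organelle-encoded genes (74 of 96, 0.42, 8.61e-13) were higher, both with adjusted p = 0.246 with an estimated correlation. By single genes edgeR called 0 of 27686 for mild salinity (4256 at an unadjusted p under 0.05, DESeq2 1011), but 5067 without well-watered replicate 3. Under mild drought proliferating markers (11 of 11, −0.59, 1.28e-07) and organelle-encoded genes (89 of 96, −0.39, 1.25e-11) were lower and secondary wall genes higher (5 of 5, 0.49, 0.00133), with adjusted p = 0.525, 0.676 and 0.525 with an estimated correlation. All 3 calls held without any 1 library. Proliferating-like nuclei were 14.7% and 12.2% there, and secondary wall-like nuclei 10.7% and 10.1% against 6.36% to 7.84% when well-watered. Abscisic acid genes rose under mild drought (13 of 16, 0.54, 0.00345, and adjusted p = 0.745 with an estimated correlation), but not without well-watered replicate 2 or mild drought replicate 2 (up to 0.968). By single genes edgeR called 0 of 27686 for mild drought (2864 at an unadjusted p under 0.05, DESeq2 220), 42 without the low GI libraries, 13 without well-watered replicate 3 and 1 without either moderate drought library.

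Between severities, the abscisic acid list was higher under moderate than mild drought (16 of 16, mean 2.08, camera adjusted p = 1.40e-12, and adjusted p = 0.421 with an estimated correlation), with RAB16B, singled out after its values were seen, at 4.07 (SE 0.57, edgeR adjusted p = 0.224). It was also higher under moderate than mild salinity (mean 0.82, 0.00115, and adjusted p = 0.486 with an estimated correlation), though not without mild salinity replicate 2 (0.227). From mild to moderate salinity all 11 proliferating markers were higher (0.57, 3.17e-05, and adjusted p = 0.297 with an estimated correlation), and proliferating-like nuclei went from 12.9% and 17.6% to 21.6% and 22.1%. Carbon fixation genes were lower (−0.90, 0.00171, and adjusted p = 0.255 with an estimated correlation), but not without mild salinity replicate 2 (0.0710). Organelle-encoded genes were higher under moderate than mild drought (0.51, 8.18e-13) and lower under moderate than mild salinity (−0.43, 7.93e-13), with adjusted p = 0.421 and 0.297 with an estimated correlation, and both held without any 1 library. Single genes between drought severities numbered 0 of 27686 by edgeR (3937 at an unadjusted p under 0.05, DESeq2 427), but 3526 without well-watered replicate 3, 9 without replicate 2 and 3 without either mild salinity library. Between salinity severities edgeR called 2 genes, Os06g0513943 (5.47, SE 0.41, 0.0251) and Os06g0493100 (5.22, SE 0.44, 0.0324), the second named after its values were seen. Both rest on moderate salinity replicate 2, at 32.3 and 9.57 CPM, since the other 3 salinity libraries held 0.704 CPM or less of each. They were also high in batch 1 without salt, at 214 and 21.9 CPM in mild drought replicate 1 and 73.0 and 8.42 in well-watered replicate 1, and the other libraries without salt held 3.18 CPM or less, so they varied between libraries within groups. With DESeq2 the count was 433. Leaving out well-watered replicate 3 gave 13, and leaving out any other library 0 or 1.

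Inside nucleus classes, pooled drought and salinity ask whether a response is shared by cell classes. Of 234 pairs of list and class, 33 passed camera for drought and 91 for salinity, and 0 did with an estimated correlation (lowest adjusted p = 0.944 and 0.352), so the list calls here hold at the preset correlation only. Abscisic acid genes were higher under drought in each of the 5 named classes, by a mean log2 of 2.24 in epidermis-like (14 of 14 higher), 2.03 in proliferating-like, 1.89 in secondary wall-like, 1.88 in mesophyll-like and 1.26 in meristem-like nuclei (camera adjusted p up to 8.99e-05, and adjusted p of at least 0.958 with an estimated correlation). Under salinity they were higher by 2.02, 2.02, 1.99, 2.10 and 1.14 in the same order (camera adjusted p up to 4.04e-06, and at least 0.352 with an estimated correlation). Free RNA could carry such changes from a class into the others, so a rise in every class does not show that every class responded. The same limit holds for the jasmonate and stress factor lists below. Proliferating markers were lower under drought in proliferating-like nuclei (11 of 11, −0.26, camera adjusted p = 0.01002, and adjusted p = 0.958 with an estimated correlation). They were also lower in the other 4 classes (to −0.64 in mesophyll-like nuclei), where free RNA, whose share was not measured, is counted too, and the same libraries held fewer proliferating-like nuclei. Jasmonate genes were lower under salinity in mesophyll-like (−1.47, 5 of 5 lower, 2.53e-07), secondary wall-like (−1.24), epidermis-like (−1.22) and proliferating-like nuclei (−0.89, 0.00074), each with adjusted p = 0.352 with an estimated correlation. Stress factors were lower in all 5 named classes (camera adjusted p up to 0.00254, and adjusted p of at least 0.352 with an estimated correlation). By single genes, edgeR made 44 calls for drought (24 genes in 9 of 13 classes) and 18 for salinity (14 genes in 5). TIP1;2 rose under drought in meristem-like nuclei (3.56, SE 0.43, adjusted p = 0.0151) and in cluster 13 (3.33, SE 0.54, 0.0151), above its batch in 4 of 4 libraries. Each of these 2 calls was past in 6 of 11 fits without 1 library, ending without any well-watered library, mild drought replicate 1 or moderate drought replicate 2 (up to 0.152 and 0.208). The call in meristem-like nuclei stood without mild drought replicate 2, in which only 1.77% of nuclei were meristem-like (3.62, adjusted p = 0.00405). Os02g0259900 rose in 5 classes, by 3.49 (SE 0.38, 0.0358) in proliferating-like nuclei, and was above its batch in 4 of 4, but past there in only 4 of 11 such fits. Os02g0603600 fell in mesophyll-like nuclei under drought (−1.92, SE 0.24, 0.0458) and salinity (−2.17, SE 0.25, 0.0342), past in 2 and 4 of 11 such fits. In epidermis-like nuclei edgeR called 0 genes for either stress (1717 and 1676 at an unadjusted p under 0.05). DESeq2, summed over the classes, called 700 for drought and 1015 for salinity.

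These class counts turned on single libraries. The 44 drought calls became 5 without moderate drought replicate 2, 9 without mild drought replicate 1, 11 without any 1 well-watered library, 74 without moderate drought replicate 1, 89 without moderate salinity replicate 1 and 632 without mild drought replicate 2. The 18 salinity calls became 1 and 495 without mild drought replicates 1 and 2, 408 and 9 without moderate drought replicates 1 and 2, and 2 and 5 without well-watered replicates 1 and 3. They became 29 and 10 without mild salinity replicates 1 and 2, and 2 and 4 without moderate salinity replicates 1 and 2.

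By severity, a fit added after the data were seen, RAB16B rose under moderate drought in epidermis-like nuclei by 6.78 (SE 0.55, edgeR adjusted p = 0.000715) and in proliferating-like nuclei by 6.08 (SE 0.51, 0.00117), and under moderate salinity by 6.24 (SE 0.56, 0.00174) in epidermis-like nuclei. The well-watered libraries held only 80, 14 and 25 UMIs of RAB16B over all nuclei, so the size of these folds is uncertain. PP2C08 rose in proliferating-like nuclei by 3.18 (SE 0.39, 0.00780) and 3.61 (SE 0.38, 0.00514) under moderate drought and salinity, and PP2C68 in secondary wall-like nuclei by 3.26 (SE 0.53, 0.0113) and 4.05 (SE 0.53, 0.00468). In whole libraries PP2C08 was past in 1 of 11 fits without 1 library for each moderate stress. PP2C68 was there far higher in moderate drought replicate 1 than in replicate 2, as given above. Calls of single genes by severity inside classes were not followed in fits without 1 library. Mesophyll-like nuclei had less DREB1A (−4.46, SE 0.56, 0.00377), DREB1B (−4.21, SE 0.49, 0.00293) and TIFY11D (−2.19, SE 0.37, 0.0165) under moderate salinity. Under mild salinity they had more RCA (1.51, SE 0.29, 0.0415). Moderate drought changed 99 genes in proliferating-like, 124 in epidermis-like, 265 in mesophyll-like, 150 in secondary wall-like and 65 in meristem-like nuclei, and moderate salinity 96, 98, 316, 182 and 89. Mild salinity changed 2, 10, 223, 55 and 2, and mild drought 1, 1, 3, 2 and 3. Summed over the 5 classes, mild drought moved from 10 to 0 without mild drought replicate 2 and 363 without well-watered replicate 2, and moderate drought from 703 to 349 and 8234 without well-watered replicates 2 and 3. Mild salinity moved from 292 to 0 without mild salinity replicate 1 and 11714 without well-watered replicate 3, and moderate salinity from 781 to 45 without moderate salinity replicate 1 and 12424 without well-watered replicate 3.

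**Figure D3:**
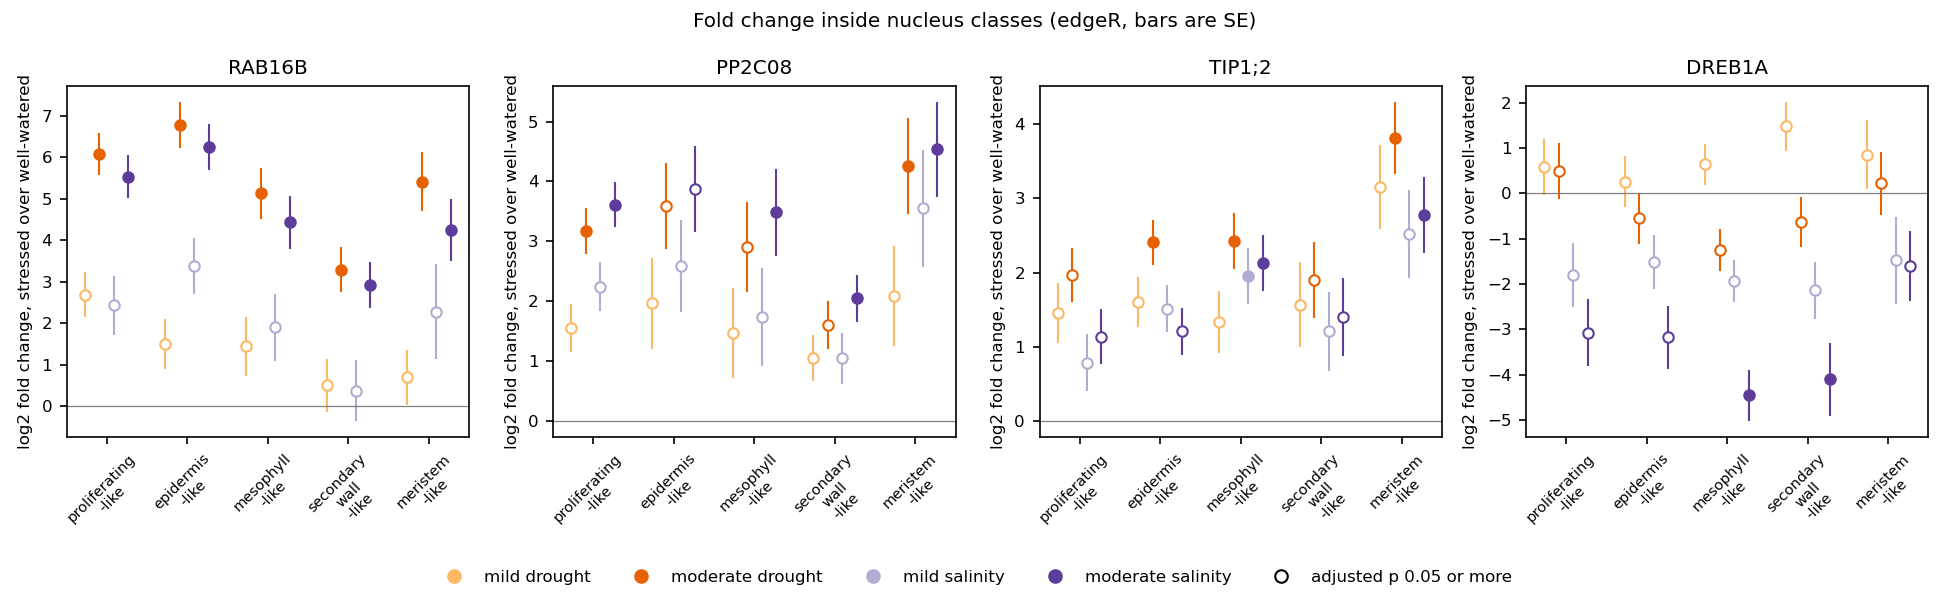
Fitted log2 fold change over well-watered (y axis, bars are SE) of 4 genes in 5 nucleus classes, coloured by stress and severity, with open symbols at an adjusted p of 0.05 or more. Under moderate drought RAB16B lies at 6.78 in epidermis-like nuclei, and DREB1A lies at −4.46 in mesophyll-like nuclei under moderate salinity.

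Whether epidermis-like and mesophyll-like nuclei responded differently was tested within libraries. Under salinity limma called 2 of 19681 genes, both lower in mesophyll-like nuclei and both named after their values were seen. Os07g0604000 was at −2.02 (SE 0.27) there and −0.46 (SE 0.20) in epidermis-like nuclei, and Os01g0132000 at −2.97 (SE 0.50) and −1.40 (SE 0.52), with limma differences of 1.52 and 1.48 (adjusted p = 0.0285). At an unadjusted p under 0.05 there were 1363 genes. The count was 0 without any 1 well-watered library, mild drought replicate 1, mild salinity replicate 1 or either moderate salinity library, and 1, 3 and 4 without moderate drought replicate 1, mild salinity replicate 2 and mild drought replicate 2. It was also 0 with no batch term, with the replicate block in place of batch and with at least 1000 UMIs per nucleus. Under drought limma called 0 genes (1001 at an unadjusted p under 0.05), and 1 without well-watered replicate 3 or mild drought replicate 2. Among lists, tested later, the organelle-encoded genes were lower in epidermis-like than mesophyll-like nuclei in their response to drought (−0.19, camera adjusted p = 2.08e-06, and adjusted p = 0.553 with an estimated correlation) and to salinity (−0.17, 8.47e-05, and adjusted p = 0.667 with an estimated correlation). The clock (0.36) and compatible solute lists (0.46) differed the other way for drought (0.0321 each, and adjusted p = 0.553 and 0.548 with an estimated correlation).

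The share of nuclei in each class asks whether stress changed the makeup of the leaf. Proliferating-like nuclei were 14.9 ± 2.20% under drought (SD, n = 4) and 20.1 ± 1.43% when well-watered (n = 3), below in 4 of 4, with an exact permutation p of 0.0571 (2-sided) and 0.429 adjusted. Secondary wall-like nuclei were 9.58 ± 1.17% and 7.19 ± 0.756%, above in 4 of 4, with an exact permutation p of 0.0571 and 0.429 adjusted. Mesophyll-like nuclei were 13.5 ± 3.66% under drought and 11.6 ± 2.88% when well-watered (exact permutation p = 0.514), epidermis-like 15.2 ± 1.17% and 15.0 ± 0.601% (0.943) and meristem-like 6.35 ± 3.54% and 6.98 ± 3.83% (0.857). Under salinity the shares were 18.5 ± 4.29% proliferating-like (exact permutation p = 0.686), 13.7 ± 0.677% epidermis-like (0.0857), 15.3 ± 3.64% mesophyll-like (0.229), 7.75 ± 1.20% secondary wall-like (0.514) and 6.60 ± 4.01% meristem-like (0.914). No share passed after adjustment, and the smallest p that 35 arrangements allow is 0.0286.

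**Figure D4:**
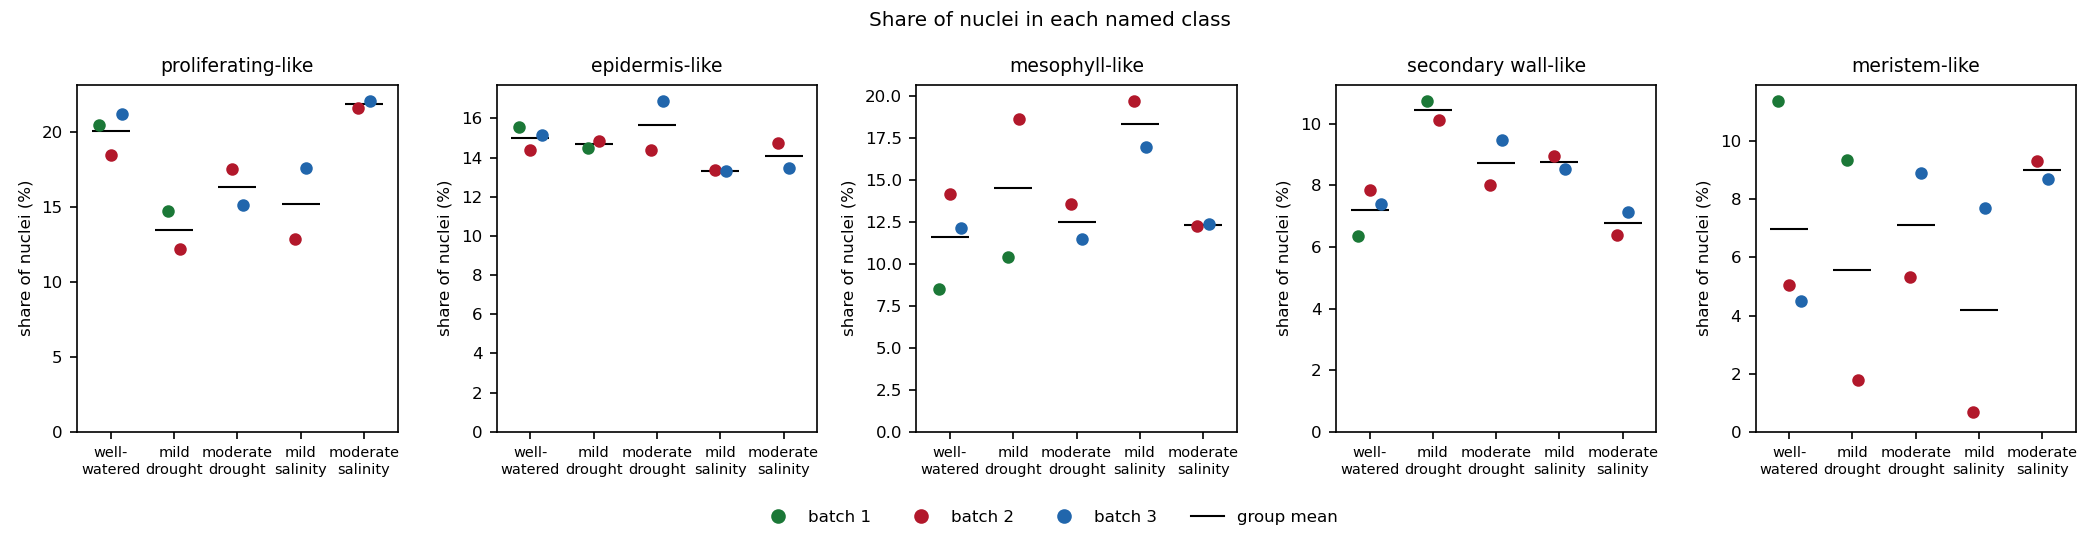
Share of nuclei in percent (y axis) of each named class in each library, by group, coloured by batch, with lines at group means. Meristem-like nuclei are 1.77% and 0.668% in mild drought replicate 2 and mild salinity replicate 1, and 4.50% or more elsewhere.

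The last comparison asks how far drought and salinity moved the same genes. Since edgeR called 0 genes for either (DESeq2 286 and 318), the shared count was 0, and drought and salinity use the same well-watered libraries as controls, which alone makes their folds alike. Across 18430 genes the folds had a covariance of 0.103, against a mean of 0.0476 and at most 0.0561 in 100 simulated data sets with no change and the same controls. Their correlation across genes, which are not independent replicates, was 0.604 against 0.565 in the simulations (0.543 to 0.607), and 61.8% of genes had the same sign against 69.0%. The covariance lay above every simulated value, the correlation within their range, and the share of equal signs below their mean. Simulated genes were drawn independently, so the simulated ranges leave out correlation between genes. Simulated libraries were drawn independently too. In the data, moderate drought replicate 1 deviated together with mild and moderate salinity replicate 1 of its batch (correlations of 0.757 and 0.848). Such shared deviations could raise the covariance, so these simulations cannot tell them from a shared response. The overlap was not examined without the libraries of low GI. Across alternatives, each set beside 25 simulations fitted the same way, only the correlation changed its place. The covariance stayed above the simulated values and the share of equal signs below them. Without well-watered replicate 3 the covariance was 0.187 (at most 0.0930 simulated), the correlation 0.726, now above the simulated range (0.699 to 0.719), and the share of equal signs 70.4% (73.6% to 75.1%). Without replicate 2 the covariance was 0.0943 (at most 0.0942) and the correlation 0.594, below the simulated range (0.703 to 0.719), and without replicate 1 they were 0.145 (at most 0.0689) and 0.687 (0.617 to 0.643). With no batch term the covariance was 0.169 (at most 0.0694), the correlation 0.694 (0.556 to 0.5998) and the share of equal signs 67.9% (68.5% to 69.8%).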

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

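The tests of a raised level in well-watered replicate 3, of the clustering and of the stress group were chosen only after the result was seen, and the remaining tests here were written down before.

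In groups of 4 libraries, a library far from the 3 others was found 4 times in 54 groups examined, and chance flags about 1 in 20 groups. Epidermis-like nuclei were 14.7% in moderate salinity replicate 1 and 13.3% to 13.5% in the other 3 salinity libraries. The aquaporin list was at a mean log2 CPM of 6.22 in moderate drought replicate 1 and at 5.06 to 5.26 in the other drought libraries. Meristem markers were at −0.24 in mild drought replicate 2 against 2.91 to 3.53 in the other drought libraries, and at −0.17 in mild salinity replicate 1 against 3.17 to 3.58 in the other salinity libraries. A difference between classes also stood out: 2 genes, Os07g0604000 and Os01g0132000, responded to salinity differently in epidermis-like and mesophyll-like nuclei (limma), with 0 to 4 called when 1 library was left out.

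The abscisic acid list was higher over well-watered in batch 2 (mean log2 3.20) than in batch 3 (1.15), a difference of 2.05 (SD 0.20 over moderate drought, mild salinity and moderate salinity). The difference was at least 1.2982 inside each of the 5 named classes, which goes against a different makeup of cell classes. The class values rest on 11 to 14 genes of the list, against 16 for all nuclei. Free RNA, whose share was not measured, could carry a difference from a class into the others, so makeup is not excluded. A raised level in the well-watered library of batch 3 is argued against, since the well-watered libraries account for 17.454% of it. The labels give a single hour early in the light period for all dissections, which goes against a different hour of sampling, but it stays a candidate explanation that the clock genes are consistent with: LHY moved by 1.0701 between the batches and PRR37, PRR73 and PRR95 the other way, by −0.74, −2.21 and −0.71, with GI at −2.95. A stronger stress in the batch 2 plants was not tested and stays open, and it could itself move the clock genes. Clock genes also differed without stress, between well-watered libraries. Replicate 1 (batch 1), with the fewest total UMIs, held 4086 of LHY against 49922 and 82214 in replicates 2 and 3. It held more GI (11071 against 3743 and 3319) and PRR95 (4930 against 1336 and 1438). PRR37 (2831 against 4375 and 5656) and PRR73 (3680 against 7761 and 6092) were lower, as its total was. This is 1 library of a batch outside the comparison, so it does not decide between hour and stress.

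Leaving out well-watered replicate 3 gave 4804 calls for moderate salinity, 4708 of them new. Inside proliferating-like nuclei leaving it out multiplied the calls summed over the 4 severities by 62.126, and by 7.23 to 35.8 in the other 4 named classes. This goes against the makeup of its cell classes, but free RNA was not measured, so makeup is not excluded. For moderate salinity alone the calls went from 96 to 4921 in proliferating-like nuclei and from 316 to 1803 in mesophyll-like nuclei, the smallest ratio of the 5. That too few libraries were left to estimate the spread cannot be told apart from a real response: 67.672% of those genes had the same sign in batch 3, whose control that fit did not use although it did use moderate salinity replicate 2, against 58.0% of all genes tested, a share between the bounds set in advance. In batch 2, whose control the fit did use, 100% had it. Well-watered replicate 3 is the only batch 3 control. Without it, a difference between batches 2 and 3 shared by the stressed groups goes into the batch term. The folds then rest mainly on batch 2. The median difference of those genes in batch 3 was 0.15 in the called direction, against a median called size of 1.03. This shrinkage goes with too few libraries, and also with a response that differed between the batches. No biological explanation was tested, since the groups name none for a single library.

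Meristem-like nuclei were few in mild drought replicate 2 (1.77%) and mild salinity replicate 1 (0.668%). A clustering that placed them elsewhere is argued against, since the 5 KNOX genes summed over all nuclei reached at most 7.9889% of the median of the other libraries. Doublet calls are argued against, since with called doublets kept the share reached at most 19.994% of that median. The stress group as the cause is argued against, since the other library of each group held at least 152.74% of the well-watered median. How much of the shoot apex each dissection took in was not measured and stays open.

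Other splits of the compared libraries into groups of the same sizes, 35 for each comparison, give counts to set beside the real ones. For the genes called under salinity inside classes 1 of 35 splits, the real one, reached 18 and the highest other 17. Chance is not taken as excluded even there, since it is 1 of 12 results examined, a margin of 1 call, and the count ran from 1 to 495 without mild drought replicates 1 and 2. Nor can chance be excluded for the rest. Where the real count was 0, every split reaches it, so those results were fixed in advance and do not bear on chance. For drought, 35 splits gave at least the real 0 genes (highest other 1689), 20 at least the real 4 lists (8), 12 at least the real 44 class calls (12162), 17 at least the real 33 class lists (50) and 35 at least the real 0 class differences (281). The split with 1689 and 12162 calls set both mild drought libraries and well-watered replicates 1 and 2 against moderate drought and well-watered replicate 3, which points to a structure of the samples. That split puts batch 1 and batch 3 wholly on opposite sides, the fit held batch as a term, and the cause of these calls was not tested. With batch 1 left out edgeR called 0 genes for the real drought comparison, as with all libraries, which does not bear on that split. For salinity, 35 splits gave at least 0 genes (highest other 2), 2 at least the real 10 lists (10), 2 at least the real 91 class lists (101) and 2 at least the real 2 class differences (12). For salinity against drought, 35 gave at least 0 genes (1) and 6 at least the real 7 lists (11).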

How the results depend on the processing

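The alternatives with only batches 2 and 3, without the libraries of low GI, with only genes listed in every library, with unlisted genes as 0 throughout, with libraries left out for single genes, with exact permutation of list means and all those by severity inside classes were chosen only after the result was seen, and the others were planned. Of the main results under alternatives, 171 values stayed within 1.5 times the reported count and 159 moved further, and 3 shares of nuclei kept their direction throughout. Counts of 0 that stayed 0 are among the 171, such as those of shares of nuclei past adjustment and of shared genes. The 11 calls of single named genes were all kept with DESeq2 and all lost with no batch term and with the replicate block. In the fits without 1 library 59 of their values stayed past the threshold and 62 did not. Without the low GI libraries the 11 calls rest on 1 moderate library per stress, so none is counted as kept or lost. With only batches 2 and 3, 4 of the calls were kept and 7 lost. No direction of these genes or shares reversed. With DESeq2 the counts were 286 for drought, 318 for salinity, 174 between them, 220 for mild drought, 814 for moderate drought, 1011 for mild salinity, 1205 for moderate salinity, 427 and 433 between severities of drought and salinity, and 700 and 1015 inside classes. Without the low GI libraries drought gave 396 and mild drought 42. With only batches 2 and 3 moderate drought gave 36, moderate salinity 0 and the salinity severities 0. With only the libraries compared mild drought gave 8, moderate drought 45 and the salinity severities 112. With no filter mild drought gave 2, mild salinity 2, moderate salinity 181 and the drought severities 2. Unlisted genes as 0 gave 1 for mild drought, 82 for moderate drought, and 1 each between severities. Only genes listed in every library gave 3 for mild salinity and 0 between its severities. With no batch term moderate drought gave 1, moderate salinity 2, the salinity severities 0, drought inside classes 2, salinity inside classes 0, class differences under salinity 0, and by severity inside classes 1 (mild drought), 5 (moderate drought), 0 (mild salinity) and 2 (moderate salinity). With at least 1000 UMIs per nucleus class differences under salinity gave 0. With an estimated correlation lists gave 0 in whole libraries and 0 inside classes. The cause was not tested for any of these. Exact permutation of list means gave 0 of 19, which for drought and salinity is nearly fixed by the design, since the smallest p possible is 0.0286 before adjustment.

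The replicate block in place of batch gave 0 for moderate drought, 0 for moderate salinity, 0 between salinity severities, 0 for drought and 0 for salinity inside classes, 1 and 0 for class differences under drought and salinity, and by severity inside classes 0, 2, 1 and 3 (mild and moderate drought, mild and moderate salinity). Deviations from group means had a mean correlation of 0.176 over 20 pairs of the same replicate number and −0.126 over 28 other pairs. By batch it was 0.460 over 17 pairs of the same batch and −0.25 over 31 others. In groups of 2 libraries the deviations mirror each other, so pairs are not separate evidence. In batches 2 and 3 the moderate drought and salinity libraries correlated at 0.757 to 0.848 with each other. With the well-watered library of their batch they correlated at only 0.0166 to 0.182. The cause of the block's counts was not tested.

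Leaving out 1 library at a time gave 0 to 6 genes for drought, 0 to 2 for salinity, 0 to 2 between them, 0 to 13 for mild drought, 19 to 2639 for moderate drought, 0 to 5067 for mild salinity, 1 to 4804 for moderate salinity, 0 to 3526 between drought severities and 0 to 13 between salinity severities. Inside classes it gave 5 to 632 for drought, 1 to 495 for salinity, 0 to 1 and 0 to 4 for class differences, 0 to 363, 349 to 8234, 0 to 11714 and 45 to 12424 by severity in the order above, 0 to 0 shares, 11 to 25 lists and 0 to 0 shared genes. The highest of these mostly came without well-watered replicate 3, and where an arm kept 1 library it was assumed to vary like the other groups. Depth limits genes near 0 counts, such as RAB16D and HKT1;5 in well-watered leaves, and inside meristem-like nuclei, which hold few UMIs in mild salinity replicate 1.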

Other observations

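The tests of these lists without single libraries were chosen only after the result was seen, as were the genes GRF1 and GRF10.

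Between severities, growth and meristem genes also moved. From mild to moderate salinity all 10 growth regulators were higher (mean log2 0.56, camera adjusted p = 0.00118, and adjusted p = 0.297 with an estimated correlation), with the growth-regulating factor genes GRF1 at 0.79 (SE 0.26) and GRF10 at 0.82 (SE 0.33), and the call held without any 1 library. The 5 meristem markers were higher (1.63, 0.00730, and adjusted p = 0.305 with an estimated correlation), with OSH1 at 1.39 (SE 0.86), but not without mild salinity replicate 1 (0.288), the library with few meristem-like nuclei. Jasmonate genes were lower in 7 of 7 (−0.85, 0.00828, and adjusted p = 0.402 with an estimated correlation), TIFY11B at −0.90 (SE 0.30), and so were mesophyll markers (−0.69, 0.00594) and the photosystem list (−0.59, 0.00730), both with adjusted p = 0.255 with an estimated correlation, while mesophyll-like nuclei went from 19.7% and 16.99% to 12.3% and 12.4%. These 3 calls ended without mild salinity replicate 2 (0.118, 0.0791 and up to 0.0717), and the last also without moderate salinity replicate 2. Mild salinity further lowered growth regulators (−0.43, 0.0204, and adjusted p = 0.328 with an estimated correlation), the clock (−0.89, 0.0261, and adjusted p = 0.297 with an estimated correlation) and stress factors (−0.89, 0.00504, and adjusted p = 0.175 with an estimated correlation) and raised aquaporins (0.36, 0.00504, and adjusted p = 0.320 with an estimated correlation). Of these, the growth and clock calls ended without mild salinity replicate 1 (up to 0.317 and 0.106), the clock also without well-watered replicate 2, and the stress factor call without mild salinity replicate 2 (0.0565).

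From mild to moderate drought, aquaporins were higher in 12 of 13 (mean log2 0.86, camera adjusted p = 0.00331) with PIP2;1 at 1.02 (SE 0.48), and the clock list was lower in 4 of 5 (−0.99, 0.0220) with GI at −2.61 (SE 0.79), each with adjusted p = 0.421 with an estimated correlation. Both ended without mild drought replicate 2 or moderate drought replicate 1 (up to 0.132 and 0.235). Growth regulators (0.43) and meristem markers (1.93) were higher (0.0220 each, and adjusted p = 0.426 with an estimated correlation), and secondary wall genes lower (−0.46, 0.0220, and adjusted p = 0.421 with an estimated correlation). Secondary wall-like nuclei were 10.7% and 10.1% under mild and 8.02% and 9.45% under moderate drought. All 3 calls ended without well-watered replicate 3 (up to 0.269 for the first 2 and 0.126 for secondary wall genes). Mild drought replicate 2 stood apart, with 1.77% meristem-like nuclei (9.36% in replicate 1, and 5.34% and 8.91% under moderate drought) and KNOX genes at 4.46% of the median of the other libraries. The growth call also ended without well-watered replicate 1, mild drought replicate 1 or moderate drought replicate 2, the meristem call without mild drought replicate 2 or moderate drought replicate 1, and the secondary wall call without well-watered replicate 1, either mild drought library or moderate drought replicate 1. Only batch 2 holds both drought severities.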
